A study of Mus musculus with 20 samples.

How the data were processed

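Messenger RNA from the neocortex of 20 male mice was measured on Affymetrix oligonucleotide arrays, one array per animal. Per the labels' protocols, RNA was extracted from frozen tissue with TRIZOL, poly(A) RNA was selected, cDNA was primed with an oligo-dT primer carrying a T7 promoter, and biotin-labelled cRNA was fragmented and hybridised. The mice were B6C3F1 hybrids, the first-generation cross of C57BL/6 and C3H parents, and were housed singly. The labels give 4 groups of 5 animals: young control, old control, old with α-tocopherol and old with a mixture of α- and γ-tocopherol. The labels state that each animal had its own array, so the p-values measure the spread between animals.

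The deposited table holds a linear signal intensity for each probe set on each array. The submitters' processing notes name GCOS, the Affymetrix operating software, without a version. Each deposited column had a 2% trimmed mean of 1000, so the deposited intensity values had been scaled to a common target before deposit. The background step, the detection calls and the probe set summary are not given in the sources used here. The table holds no logarithms and no centred genes. Because every array had the same trimmed mean, the values were used as deposited, by a rule set before the data were examined. A shift of all messenger RNA in one direction cannot be seen after such scaling, and an opposite shift can appear in genes that did not change.

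Affymetrix controls accounted for 64 probe sets and were left out of the tests. Among the other 45037, the platform annotation gave 1 gene symbol for 34945, several for 932 and none for 9160. Probe sets with several symbols or none were not named. Of those with 1 symbol, 34741 were matched by gene identifier to the RefSeq gene table of assembly GRCm38.p6 and took its symbol, and 204 kept the annotation's symbol. No genome was used, the build behind the array annotation is not given in the sources used here, and no coordinates are reported. Probe sets in the top 60% by mean log2 signal over all 20 arrays were tested, which set the limit at a signal of 184 and kept 27022 probe sets, 23453 of them with 1 symbol. Each gene was represented by its brightest probe set with 1 symbol, which gave 13351 genes. Other probe sets of a gene can measure other transcript ends and can disagree. Probe sets whose names mark possible cross-hybridisation represented Lyz1, Epcam, C1qb, Clu, H2-D1, H2-K1, H2-Aa, Grn, Vim, Cnp, Ccn1, Hsd17b7, Hspa8, Ttr, Lztr1 and Stx1a.

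Signals were transformed as log2(signal + 16). A fold change on this scale understates the change of dim genes. The mean signals given for genes are means of these log2 values turned back into signal, which lie below arithmetic means where mice differ. Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit with contrasts and eBayes with an intensity trend, over all 20 arrays with a shared estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The comparisons were old control against young control, each supplement against old control, the mixture against α-tocopherol, and the mean of both supplement groups against old control. Standard errors (SE) are those of the limma contrast with n = 5 per group.

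Fixed gene lists were written from textbook knowledge before the data were examined. There were 35 lists with 734 members, of which 611 were among the genes tested, and 34 lists had enough measured members for a test; the list of blood and erythroid genes had fewer than 3. They cover glial, neuronal, vascular, meningeal, choroid plexus and immune cell types, neighbouring brain regions, and pathways of ageing, lipid metabolism and antioxidant defence. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists within a comparison, and again with the correlation estimated for each list. Numbers of members past the threshold are given over all genes tested and adjusted over the list alone.

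The genes named in the text followed a rule set before the data were examined. For each comparison these were the 10 largest rises and the 10 largest falls among genes past the threshold or, where none passed, the 5 smallest p in each direction as values. To these were added 4 members of each called list with the smallest p in its direction. Ttpa, Sec14l2, Scarb1, Pltp, Gpx4, Sod1, Sod2 and Cat were added for the supplements, and Gfap, C4b, Apod, B2m and Mbp for age. C4b lay only on probe sets with several symbols and is not named in the results.

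An age score was computed for each mouse as the mean log2 signal of the 200 genes with the smallest p that were higher in all 3 old groups against young, minus that of the 200 that were lower. The old groups had equal weight. The choice did not compare the diets, but a gene that a supplement moved back toward young was less likely to be chosen. Scores were compared by exact two-sided permutation tests over 252 splits of 5 against 5 mice, for which the smallest possible p is 0.0079. Genes changed with age and moved the other way by a supplement were counted. The old control arrays enter both comparisons with opposite sign, so that number was set beside 100 simulations of unchanged groups, beside the number for independent lists and beside 20 splits of the old controls.

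Array measures were the 3'/5' signal ratios of β-actin and GAPDH, the 18S rRNA control, the mean log2 signal of 7 bacterial spike-in probe sets, the median signal and the highest signal. Differences of their log2 values between groups were compared by exact permutation tests, adjusted over 24 tests. The correlation of log2 signals between arrays ran from 0.947 to 0.973, and no 2 columns were identical. For arrays, the number of animals limits the precision.

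The fit was tested on simulated data for each comparison, with 200 of 13351 genes changed. For age, 76% of the genes changed 1.5-fold, 94% of those changed 2-fold and all of those changed 4-fold were recovered. For α-tocopherol the first 2 shares were 74% and 96%, and for the mixture 60% and 94%. Of genes changed by less, fewer were recovered. Genes called without a change made up 3.9% to 6.71% of the calls over the 5 comparisons. The noise was drawn independently for each gene, while the correlation estimated within a list reached 0.521, so these shares need not hold for the data. With the residuals of whole arrays, unchanged groups gave up to 295 genes called for the mixture against their age change, and up to 201 for α-tocopherol.

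The alternatives tried were other pseudocounts (1 and 64), no filter or the top 40% of probe sets, quantile normalization, equal array medians, other variance models, array weights, only the groups compared, every probe set or the mean of a gene's probe sets, the replicate number as a block, other sizes of the age score, an estimated list correlation, fry in place of camera, and leaving out each mouse in turn. Chosen after seeing the data were cyclic loess normalization, the spike-in signal, the β-actin ratio and the Ttr signal as covariates, and leaving out old control mice 3 and 5, and the relations of the 10 largest falls with the mixture to the 18S control. The closing part gives their effect.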

Results

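The data are 20 expression profiles of mouse neocortex that address how ageing changes gene expression in the brain and how dietary vitamin E given from middle age affects it. Young control mice were 5 months old and old control mice 30 months old, both on the control diet. The other 30-month-old mice received vitamin E from 15 months of age. One supplement was α-tocopherol at 1000 mg/kg. The other was a mixture of 500 mg/kg α-tocopherol and 500 mg/kg γ-tocopherol, which lacks a ring methyl group that α-tocopherol carries. Each group had 5 mice and each mouse 1 array, with a signal for each probe set of the array. All arrays had a trimmed mean signal of 1000, and their median signal averaged 321 ± 6 in young control, 292 ± 12 in old control, 296 ± 15 in α-tocopherol and 308 ± 17 in mixture mice (SD, n = 5 each).

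Glial, immune and lysosomal genes were among those higher in old than in young control neocortex, with 11 of 19 astrocyte markers, 15 of 26 lysosome and 8 of 27 interferon genes past the threshold. Of the 17 lists called, complement alone held with an estimated correlation (adjusted p = 0.0328, others 0.0979 to 0.321). With fry all 17 were called (adjusted p at most 0.0293). Gfap, the intermediate filament of astrocytes, rose 3.52-fold (log2 fold change 1.82 ± 0.18 SE, limma adjusted p = 2.34e-06). Lyz1, a lysozyme, had the largest rise, from a mean signal of 127 to 1682, back-transformed from log2 means as for all genes here (log2 fold change 3.57 ± 0.33 SE, adjusted p = 9.89e-07), on a probe set whose name marks possible cross-hybridisation, so a contribution of its paralog Lyz2 is uncertain. Trem2, a microglial receptor, rose 3.72-fold on 1 of its 2 probe sets, the other having the opposite sign, and Serpina3n, a protease inhibitor of reactive astrocytes, 3.58-fold. The largest fall was that of Epcam, an epithelial adhesion molecule, from a mean signal of 4167 to 820 (log2 fold change -2.32 ± 0.45 SE, adjusted p = 0.00111). Its probe set is also of the kind marked for cross-hybridisation, and the other of its 2 probe sets had the opposite sign.

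Of the 13351 genes tested, 1656 were higher and 1383 lower in old mice, 3039 in all, and 4895 had an unadjusted p under 0.05. The changes were small. Their median size was 0.39 on the log2 scale, and 55 rises and 32 falls exceeded 2-fold. The other genes among the 10 largest rises were Osbpl5, a lipid transfer protein (log2 fold change 1.98), the ribosomal protein gene Rpl27a (1.87), Aspg (1.68), the ribosome assembly factor Rpf2 (1.66), the transporter Abcc10 (1.62) and the phosphatase Dusp16 (1.56). Below Epcam in size of fall were Boll (-1.53), Myoz1 (-1.46), the mesenchymal homeobox gene Prrx1 (-1.45), the tight junction gene Cldn3 (-1.42), the tetraspanin Tspan32 (-1.30), Prr32 (-1.30), Kprp (-1.29), Zfp352 (-1.27) and the peroxisomal oxidase Acox2 (2.39-fold lower). Adjusted p of these genes ran from 6.14e-06 for Osbpl5 to 0.026 for Boll. For Dusp16, Myoz1 and Tspan32 1 of 2 probe sets had the direction given.

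**Figure D1:**
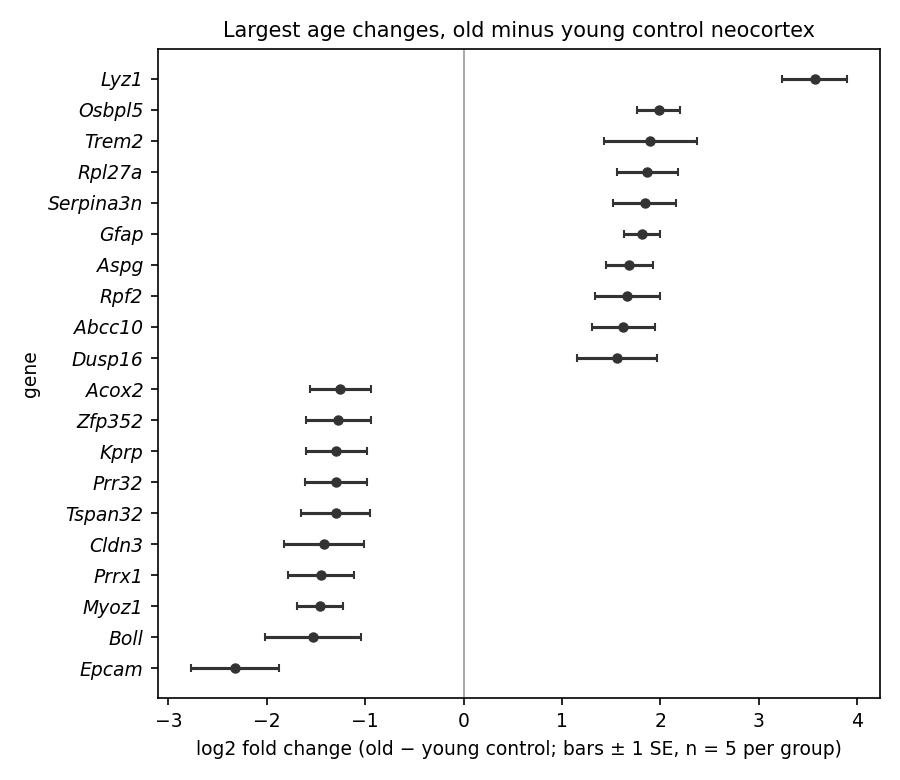
Log2 fold change, old minus young control neocortex, of the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with bars of 1 SE and n = 5 mice per group. Lyz1 lies at 3.57 and Epcam at -2.32.

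Microglial and immune lists were higher in old mice. Of the 26 measured lysosome genes 15 rose and none fell (16 and 0 adjusted over the list alone), among them Npc2, a cholesterol carrier (1.80-fold), the cathepsins Ctsd (1.58-fold) and Ctss (1.60-fold), and Grn, progranulin (1.59-fold); the list had an adjusted p of 6.3e-09, and an adjusted p = 0.0979 with an estimated correlation. Disease-associated microglia genes rose for 13 of 19 and fell for 1 (14 and 1 adjusted over the list alone, adjusted p = 6.57e-07, and adjusted p = 0.1 with an estimated correlation), including Cd52 (2.46-fold), Ctsz (1.97-fold) and the receptor Clec7a (1.74-fold). Of 20 microglia markers 9 rose and 1 fell (9 and 2 adjusted over the list alone, adjusted p = 0.000108, and adjusted p = 0.0979 with an estimated correlation), with Tyrobp, the signalling adaptor of Trem2, 1.78-fold, Ly86 1.67-fold, Sall1 1.65-fold and Olfml3 1.41-fold higher. Complement was the list called also with an estimated correlation (adjusted p = 0.0328; 0.000345 with the preset one). Its 3 C1q chains rose, C1qa 1.99-fold, C1qb 1.99-fold and C1qc 2.05-fold, with Clu, clusterin, 1.41-fold higher, and 4 of 12 members rose in all (7 adjusted over the list alone).

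Antigen presentation genes followed. Of 11 MHC class I genes 7 rose (8 adjusted over the list alone, adjusted p = 6.94e-06, and adjusted p = 0.157 with an estimated correlation), with H2-D1 2.04-fold, H2-K1 1.87-fold, the immunoproteasome subunit Psmb9 2.03-fold and the peptide transporter Tap2 1.58-fold higher. B2m, the light chain of class I molecules, rose 1.34-fold (adjusted p = 0.00684). Of 7 MHC class II genes 5 rose (5 adjusted over the list alone, adjusted p = 0.00278, and adjusted p = 0.176 with an estimated correlation), including H2-Ab1 (2.46-fold), Cd74, the invariant chain (1.81-fold), and H2-Aa (1.64-fold). Of 27 interferon response genes 8 rose (11 adjusted over the list alone, adjusted p = 5.59e-06, and adjusted p = 0.321 with an estimated correlation), with Bst2 2.84-fold, Ifitm3 2.12-fold, Ifitm2 1.77-fold and Ifi27 1.41-fold higher. Without old control mouse 3 the mean of the interferon list went from 0.59 to 0.30 (adjusted p = 0.000717), and Ifitm3 from 1.08 to 0.71 on the log2 scale (adjusted p = 0.00043).

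Astrocyte and oligodendrocyte genes were higher as well. Of 19 astrocyte markers 11 rose (12 adjusted over the list alone, adjusted p = 6.94e-06, and adjusted p = 0.157 with an estimated correlation), with Glul, glutamine synthetase, 1.70-fold, Atp1b2 1.46-fold, the water channel Aqp4 1.45-fold and the glutamate transporter Slc1a2 1.28-fold higher. Of 16 reactive astrocyte genes 7 rose (8 adjusted over the list alone, adjusted p = 0.000108, and adjusted p = 0.222 with an estimated correlation), among them Vim, vimentin (2.28-fold), and S1pr3 (1.60-fold). Of 20 myelin and oligodendrocyte genes 10 rose and none fell (10 and 1 adjusted over the list alone, adjusted p = 0.000108, and adjusted p = 0.176 with an estimated correlation). Apod, a lipid carrier, rose 2.11-fold (log2 fold change 1.08 ± 0.11 SE, adjusted p = 3.56e-06), Plekhb1 1.84-fold, the myelin genes Mobp and Cnp 1.58-fold and 1.43-fold, and Mbp, myelin basic protein, 1.29-fold (adjusted p = 0.0106). Of 14 oligodendrocyte precursor genes 5 rose (6 adjusted over the list alone, adjusted p = 0.0404, and adjusted p = 0.187 with an estimated correlation), with Olig1 and Bcas1 1.44-fold, Ccnd1 1.23-fold and Lhfpl3 1.22-fold higher; the list lost its call with the replicate number as a block and without old control mouse 2 or young mouse 3 or 4. The means over all probe sets of Slc1a2, Lhfpl3 and the neuronal gene Rbfox3 had the opposite direction.

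Cholesterol biosynthesis genes rose for 8 of 20 and fell for none (11 and 0 adjusted over the list alone, adjusted p = 7.01e-05, and adjusted p = 0.0979 with an estimated correlation), with the sterol sensor partner Insig1 1.84-fold, Tm7sf2 1.45-fold, Fdps 1.43-fold and Mvd 1.40-fold higher. Activity-regulated immediate early genes fell for 9 of 24 and rose for none (10 and 0 adjusted over the list alone, adjusted p = 0.000266, and adjusted p = 0.321 with an estimated correlation). In this list Btg2 fell by 1.10, Ccn1 by 0.76, the transcription factor Junb by 0.75 and the neurotrophin Bdnf by 0.37 on the log2 scale. The list of p53, DNA damage and cell cycle arrest genes was lower, with 2 of 20 higher and 5 lower over all genes and over the list alone (adjusted p = 0.0433, and adjusted p = 0.182 with an estimated correlation). Its members with the smallest p were Btg2, an antiproliferative gene that is also activity-regulated, the cell cycle inhibitor Cdkn1b (log2 fold change -0.38), Gadd45g (-0.49) and Sesn1 (-0.22). This list lost its call after quantile or cyclic loess normalization, with the replicate number as a block, and without old control mouse 1, 2 or 4 or young mouse 2 or 3.

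Abundant neuronal and mitochondrial genes were modestly higher as deposited, but the pan-neuronal list turned direction after quantile or cyclic loess normalization and the mitochondrial list after quantile normalization. These lists and the presynaptic one were called after neither, and the pan-neuronal list was not called with the β-actin covariate. Of 46 mitochondrial oxidative phosphorylation genes 16 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 2.53e-05, and adjusted p = 0.321 with an estimated correlation), with Ndufv2 1.40-fold, Atp5d 1.37-fold, Sdha 1.33-fold and Ndufv1 1.32-fold higher. Of 19 pan-neuronal genes 8 rose (8 adjusted over the list alone, adjusted p = 0.00873, and adjusted p = 0.321 with an estimated correlation), among them Celf4 (1.36-fold), Syt1 (1.30-fold), Tubb3 (1.24-fold) and Rbfox3 (1.19-fold). Of 18 presynaptic and vesicle genes 6 rose (8 adjusted over the list alone, adjusted p = 0.00049, and adjusted p = 0.146 with an estimated correlation), with the vesicular glutamate transporter Slc17a7 1.55-fold, Unc13a 1.31-fold, Sv2b 1.24-fold and Cplx1 1.24-fold higher. The other 17 lists, which included the antioxidant genes, vitamin E and lipoprotein handling, and GABAergic interneuron, endothelial, choroid plexus and hippocampal markers, had adjusted p from 0.0539 to 0.923.

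Among the array measures the 18S control and the median signal differed with age past the threshold, and the β-actin ratio did not. The median signal was lower in old control mice (exact permutation p = 0.00794, adjusted p = 0.0272). The 18S rRNA control averaged 620 ± 171 in young and 1648 ± 365 in old control mice (SD, n = 5 each; exact permutation p = 0.00794, adjusted p = 0.0272), and the β-actin 3'/5' ratio 1.52 ± 0.14 and 2.04 ± 0.34 (exact permutation p = 0.0238, adjusted p = 0.0635). With the log2 β-actin ratio as a covariate, chosen after seeing the data, 1158 genes were called. With array medians set equal, the median of all genes moved from -0.02 to 0.11 and 87.8% of the 3543 calls were higher, against 54.5% as deposited. The share was 57.0% after quantile and 57.5% after cyclic loess normalization. With every probe set tested on its own there were 5097 calls.

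The comparison of α-tocopherol with old control mice asks what a supplement of α-tocopherol alone changes in old neocortex. No gene passed the threshold. The genes with the smallest p and a higher signal were Ogn, a matrix proteoglycan of the meninges (log2 fold change 0.76 ± 0.17 SE), Sft2d2 (0.61), the semaphorin receptor Nrp1 (0.51), Pcolce, which aids collagen processing (0.91), and elastin, Eln (0.44). Those with a lower signal were Vps72 (-0.29), Vezt (-0.34), Abraxas2 (-0.35), the sorting nexin Snx9 (-0.33) and the heme oxygenase Hmox2 (-0.23). In limma 0 of 13351 genes were called, the lowest adjusted p was 0.829, and 753 genes had an unadjusted p under 0.05 where 668 are due to chance. The interval of the difference lay within 1.5-fold for 88.0% of the genes and within 2-fold for 98.0%.

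Genes that carry vitamin E or that belong to antioxidant defence had log2 differences near 0. They were 0.03 ± 0.18 for Ttpa, the α-tocopherol transfer protein, -0.10 ± 0.08 for Sec14l2, -0.07 ± 0.12 for Scarb1, a lipoprotein receptor, and 0.11 ± 0.11 for Pltp, the phospholipid transfer protein (SE, n = 5 per group). The antioxidant enzymes had 0.05 ± 0.07 for Gpx4, -0.13 ± 0.08 for Sod1, -0.16 ± 0.09 for Sod2 and 0.11 ± 0.12 for Cat, with adjusted p of 0.868 or more, and the sign of Ttpa turned after cyclic loess normalization. Neither list was called, at an adjusted p of 0.679 for vitamin E and lipoprotein handling and 0.63 for antioxidant genes.

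Camera called 5 lists, none of whose members passed the threshold over all genes, and none held with an estimated correlation. Meninges genes were higher as a list (13 measured, 4 past the threshold adjusted over the list alone, adjusted p = 2.15e-09, and adjusted p = 0.0879 with an estimated correlation). Ogn was at 0.76, Slc6a13 at 0.60, Fmod at 0.58 and Islr at 0.42. Choroid plexus genes were higher as a list (9 measured, 0 past the threshold adjusted over the list alone, adjusted p = 3.83e-05, and adjusted p = 0.517 with an estimated correlation). Sostdc1 was at 1.85, Kl, klotho, at 0.99, Ttr, transthyretin, at 0.85 and Cldn2 at 0.37. These are markers of tissue next to the neocortex, and the Ttr signal of single old control mice ran from 8129 to 50082. Heat shock and chaperone genes were lower as a list (24 measured, 0 past the threshold adjusted over the list alone, adjusted p = 0.000941, and adjusted p = 0.689 with an estimated correlation). Hspa1a was at -0.29, Ahsa1 and Hsph1 at -0.18 and Hspa8 at -0.16. Cholesterol biosynthesis was lower (20 measured, 0 past the threshold adjusted over the list alone, adjusted p = 0.00699, and adjusted p = 0.526 with an estimated correlation). Hsd17b7 was at -0.25, Cyp51 at -0.22 and Mvd and Hmgcs1 at -0.14. Interferon response genes were lower (27 measured, 0 past the threshold adjusted over the list alone, adjusted p = 0.000939, and adjusted p = 0.845 with an estimated correlation). Gbp3 was at -0.50, Ifi35 at -0.33, Irf1 at -0.32 and Ifi27 at -0.21. Without old control mouse 3 the interferon list turned to a mean of 0.05 and the heat shock list was no longer called, and cholesterol biosynthesis was not called without mouse 4 or mouse 5. With fry 0 lists were called, the interferon and heat shock lists were not with the β-actin ratio as a covariate, and the interferon and choroid plexus lists were not with the Ttr signal, both chosen after seeing the data. The loss of the choroid plexus call is largely built in, since Ttr is itself a gene of that list. Without old control mice 3 and 5 the interferon list turned to 0.04 and the heat shock list was not called.

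The comparison of the mixture with old control mice asks the same of α- and γ-tocopherol together. Klotho, Kl, a gene of the choroid plexus, rose from a back-transformed mean signal of 153 to 455, with single old controls from 65.1 to 547 (log2 fold change 1.48 ± 0.36 SE, adjusted p = 0.0247). Rpf2 fell from 2371 to 710 (-1.72 ± 0.33 SE, adjusted p = 0.00917) and Rpl27a from 2864 to 1068 (-1.41 ± 0.31 SE, adjusted p = 0.0148), both of which had risen with age. As deposited 16 of 46 mitochondrial respiratory chain and 7 of 19 pan-neuronal genes fell, for example Cox5a by 1.33-fold and Snap25, a synaptic membrane fusion protein, by 1.35-fold. Both lists turned direction relative to other genes after quantile normalization and had an adjusted p = 0.237 with an estimated correlation. Sod1, the cytosolic superoxide dismutase, fell by 0.39 on the log2 scale (SE 0.08, adjusted p = 0.0144).

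Of 13351 genes, 181 were higher and 422 lower, 603 in all, and 2550 had an unadjusted p under 0.05. With array medians set equal, 33 were higher and 644 lower, 4.87% higher against 30.0% as deposited, and the median of all genes moved from 0.00 to -0.07. The share moved the other way after quantile normalization (31 higher and 51 lower, 37.8%) and cyclic loess (39 and 52, 42.9%). The median size of the 603 was 0.36 on the log2 scale, and 4 rises and 3 falls exceeded 2-fold. The other large rises were Shox2 (1.55), Tspan32 (1.38), Il1f10 (1.11), Prdm6 (0.97), Myoz1 (0.86), Ppp4r4 (0.75), the actin-binding Synpo2 (0.72), Wfdc2 (0.69) and Zic1, a transcription factor expressed in meninges (0.66). The other large falls were Tmem181a (2-fold lower), Gm16740 (-0.92), Setd4 (-0.85), Arglu1 (-0.81), Lztr1 (-0.81), the chemokine-scavenging receptor Ackr4 (-0.80), Dnajc17 (-0.80) and Marf1 (-0.76). Adjusted p of these genes ran from 0.00611 for Setd4 to 0.0437 for Ppp4r4. For Shox2, Myoz1 and Arglu1 1 of 2 probe sets had the direction given, and for Marf1 1 of 3. Within groups Tmem181a followed the log2 18S signal (Pearson r = 0.778, permutation p = 0.0008, Spearman rho = 0.738, permutation p = 0.0009, 0.624 without the 2 farthest mice, adjusted p = 0.004, n = 20). So did Arglu1 (r = 0.813, permutation p = 0.0005, rho = 0.762, permutation p = 0.0001, 0.605 without the 2 farthest mice, adjusted p = 0.004). These were 2 of 10 relations, 1 for each of the largest falls, tested after seeing the data. Rpl27a was at r = 0.625 (permutation p = 0.0314, rho = 0.466, permutation p = 0.0602, 0.175 without the 2 farthest mice, adjusted p = 0.105). Rpf2 was at r = 0.352 (permutation p = 0.218, rho = 0.134, permutation p = 0.622, -0.147 without the 2 farthest mice, adjusted p = 0.311).

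**Figure D2:**
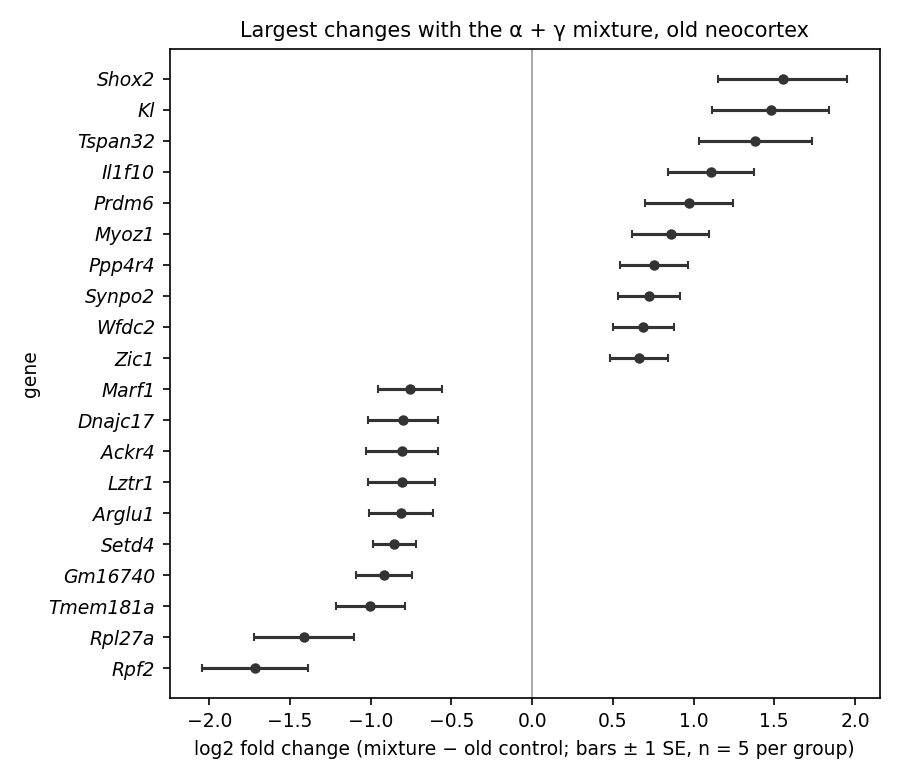
Log2 fold change, mixture minus old control neocortex, of the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with bars of 1 SE and n = 5 mice per group. Shox2 lies at 1.55 and Rpf2 at -1.72.

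The arrays of the mixture group differed from those of old controls in the measures that follow RNA and hybridisation. The β-actin 3'/5' ratio averaged 1.43 ± 0.14 against 2.04 ± 0.34, the 18S control 910 ± 162 against 1648 ± 365, the spike-in signal 11.17 ± 0.15 against 11.82 ± 0.16 on the log2 scale and the highest signal 36713 ± 2249 against 50321 ± 8974 (SD, n = 5 each). Each of these had an exact permutation p = 0.00794, the smallest the design allows, and an adjusted p = 0.0272. In the tenth of the genes with the highest signal 3 were called higher and 285 lower, with a median log2 fold change of -0.14, against 4 and 1 and a median of 0.06 in the tenth with the lowest.

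**Figure D3:**
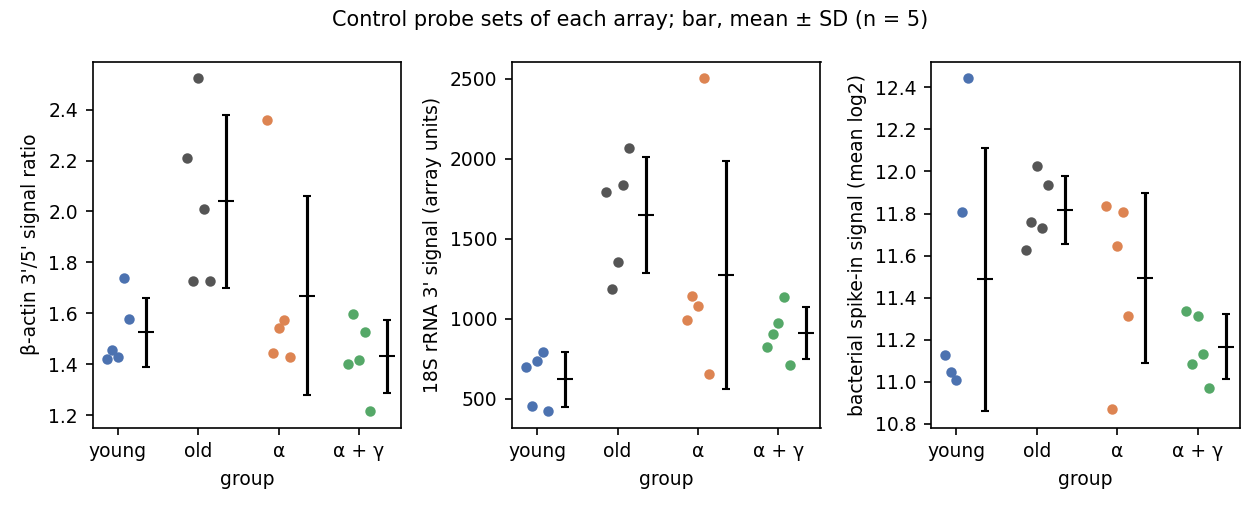
β-actin 3'/5' signal ratio, 18S rRNA signal in array units and mean log2 spike-in signal of each array by group, with bars for the mean ± SD of 5 arrays. The β-actin ratio averaged 2.04 in old control and 1.43 in mixture mice.

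Of the 9 lists called for the mixture none held with an estimated correlation. The mitochondrial, pan-neuronal and presynaptic lists were lower as deposited and turned direction relative to other genes after quantile normalization. The glutamate receptor and heat shock lists kept their direction but lost their calls. After cyclic loess normalization the same 5 lists lost their calls, and the immediate early, cholesterol, choroid plexus and meninges lists kept theirs under both. Mitochondrial oxidative phosphorylation genes fell for 16 of 46 (23 adjusted over the list alone, adjusted p = 4.74e-13, and adjusted p = 0.237 with an estimated correlation), among them Atp5h (1.38-fold), Cox7a2 (1.31-fold) and Ndufa1 (1.27-fold lower), though Cox7a2 turned to 0.01 on the log2 scale after quantile normalization. Pan-neuronal genes fell for 7 of 19 (12 adjusted over the list alone, adjusted p = 3.17e-07, and adjusted p = 0.237 with an estimated correlation). Snap25 was at -0.43, the neuronal splicing factor Rbfox3 at -0.35, the vesicle fusion ATPase Nsf at -0.33 and Celf4 at -0.31. Presynaptic and vesicle genes fell for 4 of 18 (6 adjusted over the list alone, adjusted p = 0.000913, and adjusted p = 0.237 with an estimated correlation), with syntaxin, Stx1a, at -0.47, Cplx1 at -0.31, Syp, synaptophysin, at -0.25 and Vamp2 at -0.20; Cplx1 and Vamp2 turned to 0.02 and 0.04 after quantile normalization. Glutamate receptor and postsynaptic genes fell for 2 of 21 (2 adjusted over the list alone, adjusted p = 0.00893, and adjusted p = 0.237 with an estimated correlation), which were Grik2 (-0.60) and Gria2 (-0.24), while Grm2 at -0.29 and Camk2b at -0.18 did not pass. The spike-in signal and the β-actin ratio were lower in the same mice.

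Heat shock and chaperone genes fell for 4 of 24 (5 adjusted over the list alone, adjusted p = 0.000297, and adjusted p = 0.4 with an estimated correlation), Hspa8 by 0.46, Ahsa1 by 0.34, Hsp90aa1 by 0.29 and Hsph1 by 0.29 on the log2 scale. The list mean went from -0.14 to -0.09 without old control mouse 3. Cholesterol biosynthesis genes fell for 2 of 20 (3 adjusted over the list alone, adjusted p = 0.00413, and adjusted p = 0.279 with an estimated correlation), Hsd17b7 by 0.41 and Hmgcs1, an early enzyme of the pathway, by 0.38, with Idi1 at -0.38 and Mvd at -0.20. Immediate early genes fell for 1 of 24, Junb, by 0.74 (9 lower and 1 higher adjusted over the list alone, adjusted p = 0.0102, and adjusted p = 0.765 with an estimated correlation). Fos was at -0.80, Arc at -0.74 and Ccn1 at -0.70. Choroid plexus genes rose for 1 of 9, Kl (4 adjusted over the list alone, adjusted p = 0.000474, and adjusted p = 0.34 with an estimated correlation). Sostdc1 was at 2.08, the channel subunit Kcne2 at a 2.38-fold higher level and Cldn2 at 0.55. Meninges genes rose for 2 of 13, Ogn (0.60) and Islr (0.44) (2 adjusted over the list alone, adjusted p = 0.0195, and adjusted p = 0.51 with an estimated correlation). Fmod was at 0.37 and Igfbp2 at 0.27. The meninges list lost its call without mixture mouse 2 or old control mouse 4 or 5, and the immediate early list without mixture mouse 3 or 5 or old control mouse 5. With fry 5 lists were called, without the immediate early, heat shock, choroid plexus and meninges lists, and the last 3 of these were not called with the β-actin covariate. The meninges list was not called with the Ttr covariate, and the meninges and heat shock lists were not without old control mice 3 and 5.

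**Figure D4:**
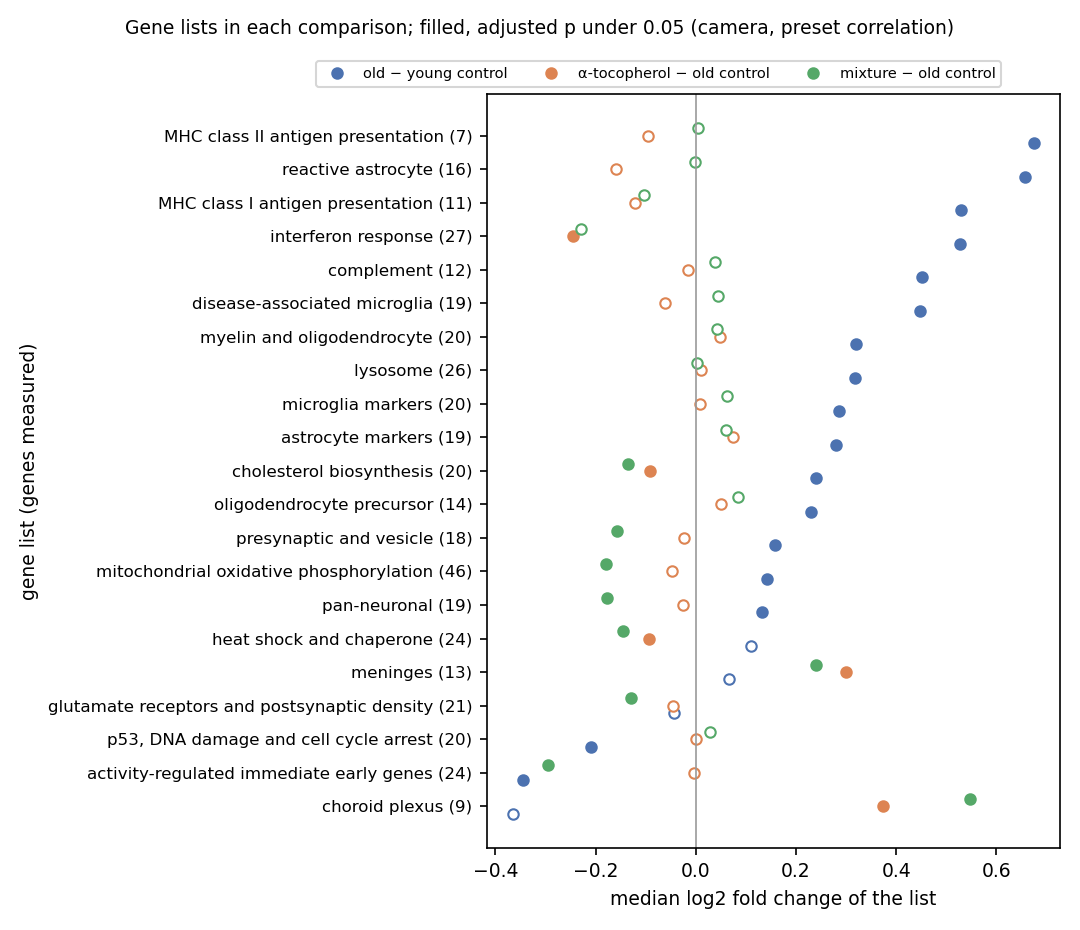
Median log2 fold change of each list called in any of old minus young control, α-tocopherol minus old control and mixture minus old control (n = 5 mice per group), with filled points for an adjusted p under 0.05 in camera with the preset correlation. The mitochondrial list lies at 0.14 for age and -0.18 for the mixture, and turned direction relative to other genes after quantile normalization in both.

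The vitamin E and lipoprotein list (adjusted p = 0.881, with a mean of 0.02 where the test's direction was down) and the antioxidant list (adjusted p = 0.184) were not called for the mixture. Ttpa was at 0.02 ± 0.18, Sec14l2 at -0.15 ± 0.08, Scarb1 at 0.05 ± 0.12, Pltp at -0.07 ± 0.11, Gpx4 at 0.00 ± 0.07, Sod2 at -0.23 ± 0.09 and Cat at 0.00 ± 0.12 on the log2 scale (SE, n = 5 per group), with adjusted p of 0.119 or more, and the signs of Ttpa, Scarb1, Pltp, Gpx4 and Cat turned under at least 1 other scaling. The 603 calls became 82 after quantile normalization, 75 of them shared, and 0 with the spike-in signal or the β-actin ratio as a covariate and 0 without old control mice 3 and 5, at an unchanged threshold in limma and all chosen after seeing the data except quantile normalization. The genes kept part of their size where no call was left. The median size of the 603 was 0.36 as deposited (median SE 0.0865), 0.28 with the spike-in covariate (0.099), 0.23 with the β-actin covariate (0.107) and 0.32 without mice 3 and 5 (0.0967, 3 old controls left). At an unadjusted p under 0.05 there were 1417, 897 and 2145 genes. The 603 became 239 without old control mouse 3, 294 without mouse 4, 359 without mouse 5, 375 without mixture mouse 4 and 186 without mixture mouse 5. They became 91 after cyclic loess normalization, 358 with the Ttr covariate, 311 in eBayes without the trend, 319 with only the groups compared, 285 over the mean of a gene's probe sets and 970 with every probe set on its own.

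The direct comparison of the mixture with α-tocopherol asks whether diets with and without γ-tocopherol differ, at equal total tocopherol but with α-tocopherol at 500 against 1000 mg/kg. No gene passed the threshold. As deposited 5 lists were lower with the mixture, none of which held with an estimated correlation (adjusted p from 0.0809 to 0.743). The immediate early list was called also after quantile and after cyclic loess normalization, but not with fry (adjusted p = 0.609). The other 4 were called after neither but were with fry (adjusted p = 0.00792 to 0.0341), and the mitochondrial list turned direction after quantile normalization. The genes with the smallest p were, with a higher signal in the mixture group, the potassium channel Kcnd3 (0.34), the glycolytic regulator Pfkfb3 (0.64), Herc3 (0.33), Snx9 (0.38) and Myoz1 (1.01). With a lower signal they were the noncoding RNA Norad (-0.33), Rtn3 (-0.36), the malate dehydrogenase Mdh2 (-0.46), Snap25 (-0.39) and Eif5a (-0.33). In limma 0 of 13351 genes were called, the lowest adjusted p was 0.113 and 1163 genes had an unadjusted p under 0.05. The interval of the difference lay within 1.5-fold for 87.3% of the genes and within 2-fold for 98.1%, so larger differences were excluded for most genes and smaller ones were not.

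Mitochondrial oxidative phosphorylation genes were lower as a list as deposited and were not called after quantile normalization (46 measured, 13 past the threshold adjusted over the list alone and 0 over all genes, adjusted p = 7.79e-16, and adjusted p = 0.144 with an estimated correlation). Atp5h was at -0.37, Cox4i1 at -0.29 and Cox7a2 and Ndufv1 at -0.28, of which Cox7a2 turned to 0.06 after quantile normalization. Pan-neuronal genes were lower (19 measured, 10 adjusted over the list alone, adjusted p = 3.46e-10, and adjusted p = 0.0809 with an estimated correlation). Tubb3 was at -0.31 and Nsf and Celf4 at -0.26. Presynaptic genes were lower (18 measured, 3 adjusted over the list alone, adjusted p = 1.46e-05, and adjusted p = 0.0974 with an estimated correlation). Stx1a was at -0.34, Syp at -0.22, Cplx1 at -0.19 and Vamp2 at -0.18. After quantile normalization Nsf, Vamp2 and Cplx1 turned to 0.00, 0.02 and 0.08. Glutamate receptor genes were lower (21 measured, 2 adjusted over the list alone, adjusted p = 0.0103, and adjusted p = 0.144 with an estimated correlation). Grik2 was at -0.51, Grm2 at -0.38, Gria2 at -0.17 and Gria4 at -0.13. Immediate early genes were lower (24 measured, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.00034, and adjusted p = 0.743 with an estimated correlation). Ccn1 was at -0.85, Fos at -0.81, Btg2 at -0.60 and Junb at -0.59, and this list and the glutamate receptor list were not called without mixture mouse 3. The highest signal of an array was lower in the mixture than in the α-tocopherol group (47418 ± 6970 SD, n = 5; exact permutation p = 0.0159, adjusted p = 0.0476).

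The differences of vitamin E transport and antioxidant genes between the supplements were small. On the log2 scale Ttpa was at -0.01 ± 0.18, Sec14l2 at -0.04 ± 0.08, Scarb1 at 0.13 ± 0.12, Pltp at -0.18 ± 0.11, Gpx4 at -0.05 ± 0.07, Sod1 at -0.26 ± 0.08, Sod2 at -0.08 ± 0.09 and Cat at -0.11 ± 0.12 (SE, n = 5 per group), and the sign of Gpx4 turned after quantile and cyclic loess normalization. The list of vitamin E and lipoprotein handling had an adjusted p of 0.403 and that of antioxidant genes 0.246. Without α-tocopherol mouse 5, 100 genes were called, 9 higher and 91 lower.

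The mean of both supplement groups was compared with old control to ask how supplemented mice differed on average. No gene passed. Of 9 lists called, none held with an estimated correlation (adjusted p from 0.287 to 0.845). Chaperone and cholesterol lists were lower, and choroid plexus and meninges lists were higher. Mitochondrial, pan-neuronal and presynaptic lists were lower as deposited but were not called after quantile normalization. The mean does not show what both diets share. With α-tocopherol alone the mitochondrial list averaged -0.04 (adjusted p = 0.0953), the pan-neuronal list -0.03 (0.565), the presynaptic list -0.01 (0.706) and the glutamate receptor list -0.03 (0.565), and with the mixture the interferon list averaged -0.19 (0.0949), none of them called. The genes with the smallest p and a higher signal were the synaptic adhesion gene Lrrtm3 (0.56), Nrp1 (0.54), the endoplasmic reticulum co-chaperone Dnajc3 (0.36), Kcnd3 (0.29) and Qrich1 (0.26). Those with a lower signal were the histone deacetylase Hdac7 (-0.36), Kalrn (-0.35), Clasp2 (-0.34), Nrgn, neurogranin (-0.30), and Ctxn1 (-0.25). In limma 0 of 13351 genes were called, the lowest adjusted p was 0.08 and 2022 genes had an unadjusted p under 0.05. Without α-tocopherol mouse 1, 184 genes were called, without old control mouse 2, 23, and without α-tocopherol mouse 4, 1.

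None of the 9 lists called for either supplement had a member past the threshold over all genes. The lower lists were mitochondrial oxidative phosphorylation (18 of 46 adjusted over the list alone, adjusted p = 3.21e-08, and adjusted p = 0.353 with an estimated correlation), with Cox5a at -0.28, Cox7a2 at -0.25, Ndufa1 at -0.23 and Sdha at -0.22, and pan-neuronal (4 of 19, adjusted p = 0.000121, and adjusted p = 0.287 with an estimated correlation). Snap25 was at -0.24, Rbfox3 at -0.23, Nsf at -0.20 and Celf4 at -0.18. Presynaptic genes (2 of 18, adjusted p = 0.0263, and adjusted p = 0.385 with an estimated correlation) had Stx1a at -0.31, Cplx1 at -0.21, Cplx2 at -0.18 and Syp at -0.14. These 3 lists turned direction relative to other genes after quantile normalization, and the presynaptic one also after cyclic loess, as did Syp (0.00) after quantile normalization. These and the glutamate receptor list were called after neither. Heat shock genes (3 of 24, adjusted p = 7.78e-05, and adjusted p = 0.353 with an estimated correlation) had Hspa8 at -0.31, Ahsa1 at -0.26, Hsph1 at -0.23 and Hsp90aa1 at -0.18, and the list mean went from -0.12 to -0.06 without old control mouse 3. Cholesterol biosynthesis genes (2 of 20, adjusted p = 0.0017, and adjusted p = 0.287 with an estimated correlation) had Hsd17b7 at -0.33, Idi1 at -0.27, Hmgcs1 at -0.26 and Cyp51 at -0.20.

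Interferon genes (0 of 27 adjusted over the list alone, adjusted p = 0.00899, and adjusted p = 0.845 with an estimated correlation) had Ifi27l2a at -0.58, Irf1 and Ifi35 at -0.36 and Ifi27 at -0.26, and the list turned to a mean of 0.07 without old control mouse 3. Glutamate receptor genes (0 of 21 adjusted over the list alone, adjusted p = 0.0453, and adjusted p = 0.287 with an estimated correlation) had Grik2 at -0.34, Dlg4 at -0.17, Gria2 at -0.16 and Dlg3 at -0.11. This list lost its call without α-tocopherol mouse 1 or 5, mixture mouse 3 or 5, or old control mouse 1, 2 or 5, and the presynaptic list without α-tocopherol mouse 5 or old control mouse 1 or 5. With the β-actin covariate the interferon list turned (0.07), and the pan-neuronal, presynaptic, glutamate receptor and heat shock lists lost their calls. The interferon list was not called with the Ttr covariate, nor the glutamate receptor list with the spike-in covariate or without a filter on dim probe sets. Without old control mice 3 and 5 the interferon list turned (0.06) and the presynaptic and heat shock lists lost their calls. With fry 4 lists were called, the pan-neuronal, glutamate receptor, cholesterol and meninges lists. The higher lists were choroid plexus (5 of 9 adjusted over the list alone, adjusted p = 3.85e-05, and adjusted p = 0.287 with an estimated correlation), with Sostdc1 at 1.96, Kl at 1.23, Kcne2 at 1.01 and Cldn2 at 0.46, and meninges (3 of 13 adjusted over the list alone, adjusted p = 3.85e-05, and adjusted p = 0.287 with an estimated correlation). Ogn was at 0.68, Fmod at 0.47, Islr at 0.43 and Igfbp2 at 0.25. Ttpa was at 0.02, Sec14l2 at -0.12, Scarb1 at -0.01, Pltp at 0.02, Gpx4 at 0.03, Sod1 at -0.26, Sod2 at -0.20 and Cat at 0.06, with adjusted p of 0.103 or more, and the signs of Ttpa, Pltp and Gpx4 turned under at least 1 other scaling. The vitamin E list, with a mean of 0.03 where the test's direction was down, was at an adjusted p of 1.00 and the antioxidant list at 0.234.

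The last question was whether the supplements moved age-changed genes back toward young levels. No gene changed with age was moved the other way by α-tocopherol at the threshold, and 45 were at an unadjusted p under 0.01 in both comparisons. With the mixture 312 genes moved against their age change and 6 with it. Of the 312, 241 had risen with age and 71 had fallen, where independent lists would share 52.3 and 18.7. Examples are Rpf2 and Rpl27a, higher with age and lower with the mixture, and Tspan32 and Myoz1, lower with age and higher with the mixture. Array measures moved in the same way. The β-actin 3'/5' ratio averaged 1.52 in young control, 2.04 in old control and 1.43 in mixture mice. The 18S control averaged 620, 1648 and 910 in these groups. In the tenth of the genes with the highest signal 455 rose and 58 fell with age (median log2 fold change 0.12). With the mixture 3 rose and 285 fell (median -0.14). Diet and array handling cannot be told apart here.

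The old control arrays enter both comparisons, which produces such opposition without an effect. Simulated unchanged groups gave a mean of 3.32 opposed genes, none of 100 as many as 312, and a highest of 295. The covariance of the fold changes for age and the mixture was -0.025 against -0.0114 in the simulations (SD 0.00937), with 7 of 100 at or below the observed value; for α-tocopherol it was -0.0127 against -0.0114. With the old controls split between the comparisons, the covariance averaged -0.012 for the mixture and 0.00032 for α-tocopherol over 20 splits, and the number opposed by the mixture averaged 25.4, from 0 to 110. The 312 became 37 after quantile normalization, and 0 with the spike-in signal or the β-actin ratio as a covariate and 0 without old control mice 3 and 5, where limma gave 1417, 897 and 2145 genes at an unadjusted p under 0.05 for the mixture. The median size of the mixture change of the 312 was 0.36 as deposited, 0.27, 0.22 and 0.30 in these. The 312 became 129 without old control mouse 3, 154 without mouse 4, 180 without mouse 5, 191 without mixture mouse 4 and 110 without mixture mouse 5, 42 after cyclic loess, 203 with the Ttr covariate and 484 at an unadjusted p under 0.01 in both comparisons.

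The age score, chosen blind to diet, did not separate the old groups. It averaged -0.40 ± 0.13 in young control, 0.81 ± 0.08 in old control, 0.86 ± 0.10 in α-tocopherol and 0.79 ± 0.20 in mixture mice (SD, n = 5 each). The difference from old control was 0.05 for α-tocopherol (95% interval -0.08 to 0.18, exact permutation p = 0.468) and -0.02 for the mixture (-0.25 to 0.21, exact permutation p = 0.841), against 1.21 between old and young control. The mixture differed from α-tocopherol by -0.07 (-0.30 to 0.19, exact permutation p = 0.54). After adjustment over the 3 tests, p was 0.81, 0.841 and 0.81. The intervals reach down to -21.0% of the age difference with the mixture and -6.53% with α-tocopherol, and the sign of the mixture difference depended on the choices made. It turned with 50 age genes in each direction (0.07), after quantile normalization (0.02), with every probe set (0.01) or the mean of a gene's probe sets (0.02), without mixture mouse 4 (0.01) or mouse 5 (0.04), and without old control mice 3 and 5 (0.02).

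**Figure D5:**
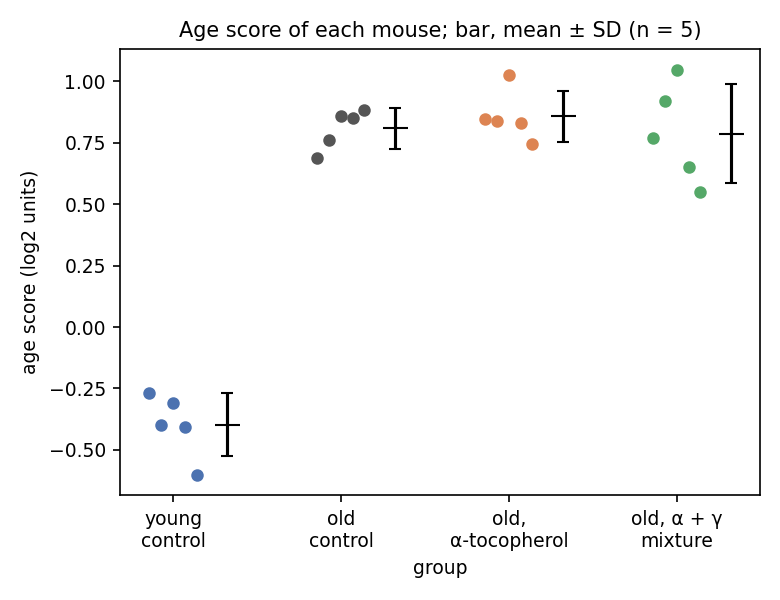
Age score of each mouse by group, in log2 units, with bars for the mean ± SD of 5 mice. Young mice average -0.40, and the 3 old groups 0.81, 0.86 and 0.79.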

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

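The tests of the effect of quantile normalization on the genes that fell, of the Y-linked genes and of Ttr in supplemented mice were chosen after their results had been seen, as were the values given for the list genes beside the genes that fell. The others were written before their results were seen, with 2 changes made afterwards. The relations with array measures were first computed on the list genes and then on the genes that fell, as the test had been worded. For the second X chromosome a deviation beyond the spread was required after a value of 0 was seen.

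Of the 422 genes that were lower in the mixture group than in old controls, 285 were in the tenth with the highest signal. The mitochondrial, pan-neuronal and presynaptic lists were lower as deposited, but were not called in camera with an estimated correlation (adjusted p = 0.237 each). Quantile normalization left 54.6% of the median log2 fold change of the 422 genes that fell (-0.35 before, -0.19 after, median SE 0.082 and 0.068), with 51 still called, while the 83 mitochondrial, pan-neuronal and presynaptic list genes went from -0.17 to 0.0021. Within groups the mean of the 422 genes followed the log2 β-actin ratio (Pearson r = 0.715, permutation p = 0.004, Spearman rho = 0.642, permutation p = 0.0081, 0.527 without the 2 farthest arrays, adjusted p = 0.01 of 5 relations) and the spike-in signal (r = 0.622, permutation p = 0.0011, rho = 0.761, permutation p = 0.0004, 0.695 without the 2 farthest, adjusted p = 0.0055), so RNA quality and hybridization are candidate explanations. An effect of the diet stays open, as 1 of 100 splits of the 10 mice, the real one, called as many genes after quantile normalization (82, highest other 4), but the spike-in signals of the groups do not overlap (11.63 to 12.03 and 10.97 to 11.34), so diet and array handling cannot be told apart. Quantile normalization would also remove a true shift of abundant genes.

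For the 83 list genes the within-group r was 0.524 with the β-actin ratio (permutation p = 0.0621, rho = 0.37, permutation p = 0.156, 0.222 without the 2 farthest arrays, adjusted p = 0.0621). With the spike-in signal it was 0.494 (permutation p = 0.0192, rho = 0.594, permutation p = 0.0063, 0.575 without the 2 farthest arrays, adjusted p = 0.024). The 181 genes that rose with the mixture kept 91.0% of their median after quantile normalization (0.39 before, 0.35 after), with 24 still called.

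Old control mouse 5 stood apart with Xist, the RNA of the inactive X chromosome, in a series of male mice (Dixon ratio 0.94; its 3 probe sets had signals of 15067.6, 2684.5 and 11558.3 against 4.2 to 114.3, 14.3 to 133.9 and 341.6 to 608 in the other mice). If RNA of a female mouse was mixed in, the rise of the 3 escape genes already seen (0.46) would need a share of 37.8%. The Y-linked genes Eif2s3y, Uty and Kdm5d argue against a share that large, as their mean was 0.0939 log2 units above the other old controls. Such a share needed a mean of -0.68 (SD 0.287). A smaller share of female RNA stays open, since the fall it needs can lie within that SD. A second X chromosome stays open. For 7 escape genes not looked at before, the mouse ranked 10.5 of 20, at 0 from its group median (highest other 0.125, SD 0.0789). The middle mouse of a group has 0 by definition. The limit written before the test would have counted 0 against a second X, but 0 was not beyond the spread. Of the 7, 6 were above the other old controls and Shroom4 was far below (-1.40), so the mean decides little. No biological explanation from the study design was tested.

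Choroid plexus genes varied between old mice, with Ttr from 8129 to 50082 in old controls. Choroid plexus tissue in the dissected sample is a candidate explanation, since Ttr followed the mean of the other choroid plexus genes within groups (Pearson r = 0.769, permutation p = 0.0061, rho = 0.728, permutation p = 0.0094, 0.856 without the 2 farthest mice, adjusted p = 0.0102, n = 20). A supplement effect on these genes cannot be told apart from it, because Ttr was 0.78 higher in the 10 supplemented than in the 5 old control mice (exact permutation p = 0.0882).

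Other divisions of the same mice into groups of the same size were counted, 100 for each result with the real one included, to see whether chance can be excluded. For the 3039 genes changed with age 1 split, the real one, gave as many (highest other 9). The same held for the 603 with the mixture (highest other 5). Young and old control 18S signals do not overlap, nor do mixture and old control spike-in signals. The other splits thus mix both kinds of array and cannot tell age or diet from array differences. Simulated unchanged groups gave up to 295 opposed genes, each of them also called for the mixture. Chance differences between arrays are therefore not excluded for the 603. For the 312 opposed by the mixture 1 split gave as many (highest other 5), which does not exclude opposition that comes from the old controls shared by both comparisons. Of the 100 simulations none gave as many as 312, and 7 had a covariance at or below the observed one. With the old controls split between the comparisons 0 to 110 were opposed. For counts of 0 the splits cannot bear on chance, since none can give fewer: 100 of 100 gave as many for α-tocopherol (highest other 7), mixture against α-tocopherol (25), either supplement (9) and genes opposed by α-tocopherol (1). For the lists chance could not be excluded: 8 splits gave as many as the 17 called for age (highest other 18), 74 as the 5 for α-tocopherol (16), 48 as the 9 for the mixture (20), 42 as the 5 for mixture against α-tocopherol (13) and 30 as the 9 for either supplement (17).

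Single mice stood apart from the 4 others of their group by the gap to the nearest over the range (Dixon ratio above 0.71), in 67 of 816 groups of values tested, 8.21%, where chance gives about 1 in 20. Old control mouse 3 had many of these among immune genes.

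Old control mouse 1 was lowest for the pan-neuronal list (0.731), Aqp4 (0.763) and Fdps (0.894). Old control mouse 2 was highest for the meninges list (0.797) and lowest for Cdkn1b (0.795) and Stx1a (0.714). Old control mouse 3 was highest for the median signal (0.769), the MHC class I antigen presentation list (0.86), the interferon response list (0.866), the reactive astrocyte list (0.849), H2-Aa (0.731), Ifitm3 (0.965), Gadd45g (0.731), B2m (0.82), Irf1 (0.786) and Ifi35 (0.825) and lowest for Abcc10 (0.715), Dusp16 (0.845), Junb (0.715) and Cat (0.899). Old control mouse 4 was highest for Clasp2 (0.804). Old control mouse 5 was highest for Mdh2 (0.864) and lowest for Sod2 (0.897).

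Young control mouse 1 was highest for Ndufv1 (0.762) and lowest for Sesn1 (0.77). Young control mouse 2 was highest for Abcc10 (0.753) and lowest for Gm16740 (0.817). Young control mouse 3 was highest for Ifitm3 (0.722) and lowest for Ifi27 (0.794). Young control mouse 5 was highest for the highest signal (0.831), Atp5h (0.797) and Hsp90aa1 (0.788) and lowest for Junb (0.764), Tmem181a (0.801) and Kcnd3 (0.757).

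α-Tocopherol mouse 1 was highest for the β-actin 3'/5' ratio (0.841) and C1qa (0.75) and lowest for the MHC class II antigen presentation list (0.761) and Cd74 (0.808). α-Tocopherol mouse 2 was lowest for Abcc10 (0.735), C1qc (0.739) and Ttr (0.759). α-Tocopherol mouse 3 was highest for the disease-associated microglia list (0.714) and Cldn3 (0.765) and lowest for the complement list (0.743), the microglia markers list (0.722) and Lztr1 (0.786). α-Tocopherol mouse 4 was highest for the 18S signal (0.738) and Insig1 (0.802). α-Tocopherol mouse 5 was lowest for Slc1a2 (0.744), Ccnd1 (0.729), Gm16740 (0.786) and Igfbp2 (0.815).

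Mixture mouse 1 was lowest for Slc17a7 (0.782). Mixture mouse 2 was highest for the presynaptic and vesicle list (0.746) and Islr (0.855). Mixture mouse 3 was highest for Gfap (0.734), Tyrobp (0.775) and S1pr3 (0.793) and lowest for Btg2 (0.755) and Gria4 (0.828). Mixture mouse 4 was highest for Unc13a (0.719) and lowest for Syt1 (0.775). Mixture mouse 5 was highest for Zfp352 (0.792) and lowest for Ndufv2 (0.786) and Setd4 (0.721).

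The effects of the mixture and of α-tocopherol, each against old control, differed in mean log2 fold change for 5 lists by the camera test of the difference: -0.16 for pan-neuronal, -0.12 for presynaptic, -0.11 for glutamate receptor, -0.26 for immediate early and -0.15 for mitochondrial genes, none of which held with an estimated correlation. The 18S rRNA control, outside the messenger RNA measurement, was 1.43 log2 units higher in old than in young controls.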

How the results depend on the processing

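Cyclic loess normalization, the spike-in, β-actin and Ttr covariates and leaving out old control mice 3 and 5 were chosen after seeing the data; the others were planned. The number of genes changed with age stayed within 1.5 times 3039 in all alternatives except every probe set and the β-actin covariate. The numbers for the mixture and for opposed genes depend on the scaling, the array measures and single mice, and the cause was not tested. Of the 603 mixture genes 75 were among the 82 called after quantile normalization and 81 among the 91 after cyclic loess, and of the 3039 age genes 2457 and 2375 were shared. Directions relative to other genes are meant for lists, with the mean of the list in brackets. Dim genes lie close to the background, where the signal limits the precision.

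Without a filter on dim probe sets there were 9 lists for mixture against α-tocopherol and 3 either-supplement genes. After quantile normalization there were 82 mixture genes, 2 lists for mixture against α-tocopherol and 37 genes opposed by the mixture, and the mixture minus old control age score turned to 0.0161. The direction changed for the pan-neuronal list (-0.0358) and the mitochondrial oxidative phosphorylation list (-0.00646) in age. So did Cplx1 (0.0194), Vamp2 (0.0417), Cox7a2 (0.0119), Ttpa (-0.0463), Cat (-0.0220), the pan-neuronal list (-0.0148), the presynaptic and vesicle list (-0.00825) and the mitochondrial oxidative phosphorylation list (-0.00692) for the mixture. For mixture against α-tocopherol this held for Nsf (0.000119), Vamp2 (0.0219), Cplx1 (0.0833), Cox7a2 (0.0559), Gpx4 (0.0963) and the mitochondrial oxidative phosphorylation list (-0.00222). Syp (0.00334), Ttpa (-0.0186), the pan-neuronal list (-0.00396), the presynaptic and vesicle list (0.00168) and the mitochondrial oxidative phosphorylation list (-0.00580) turned for either supplement. With equal array medians direction turned for Ttpa (-0.0524), Scarb1 (-0.0226), Gpx4 (-0.0754) and Cat (-0.0733) in the mixture. For either supplement this held for Ttpa (-0.0247), Pltp (-0.0303) and Gpx4 (-0.0223). In eBayes without the trend there were 311 mixture genes. With array weights direction turned for Ttpa (-0.0480) in α-tocopherol. So did Ttpa (-0.0388), Gpx4 (-0.00315) and Cat (-0.0269) for the mixture. For mixture against α-tocopherol this held for Ttpa (0.00917). Ttpa (-0.0434) and Pltp (-0.0585) turned for either supplement. With only the compared groups in the fit there were 319 mixture genes. With every probe set tested on its own there were 5097 age genes, 970 mixture genes and 1 either-supplement gene, and the mixture minus old control age score turned to 0.0124. Over the mean of a gene's probe sets there were 285 mixture genes, and the mixture minus old control age score turned to 0.0188. The direction changed for Slc1a2 (-0.00652), Lhfpl3 (-0.00258) and Rbfox3 (-0.0849) in age. For the mixture this held for Vamp2 (0.00469), Scarb1 (-0.0919), Pltp (0.0798) and Gpx4 (-0.19). Gria4 (0.0440) turned for mixture against α-tocopherol. So did Gpx4 (-0.0791) for either supplement. With the replicate number as a block there was 1 mixture against α-tocopherol gene and 3 either-supplement genes. With 50 age genes in each direction the mixture minus old control age score turned to 0.0653. At an unadjusted p under 0.01 in both there were 45 genes opposed by α-tocopherol and 484 genes opposed by the mixture. With a correlation estimated for each list there was 1 list for age, 0 lists for α-tocopherol, 0 lists for the mixture, 0 lists for mixture against α-tocopherol and 0 lists for either supplement. With fry there were 0 lists for α-tocopherol, 5 lists for the mixture and 4 lists for either supplement.

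After cyclic loess normalization there were 91 mixture genes, 5 lists for the mixture, 1 list for mixture against α-tocopherol, 5 lists for either supplement and 42 genes opposed by the mixture. The direction changed for the pan-neuronal list (-0.00940) in age. Ttpa (-0.00678) turned for α-tocopherol. So did Ttpa (-0.0646), Pltp (0.0235) and Cat (-0.0216) for the mixture. For mixture against α-tocopherol this held for Gpx4 (0.0704). Ttpa (-0.0357) and the presynaptic and vesicle list (-0.00129) turned for either supplement. With the spike-in signal as a covariate there were 0 mixture genes and 0 genes opposed by the mixture. A turn was seen for Cat (-0.0164) in the mixture. For mixture against α-tocopherol this held for Ttpa (0.00508). Scarb1 (0.0152) turned for either supplement. With the β-actin ratio as a covariate there were 1158 age genes, 3 lists for α-tocopherol, 0 mixture genes, 8 lists for mixture against α-tocopherol and 0 genes opposed by the mixture. Direction turned for Ttpa (-0.18) in α-tocopherol. For the mixture this held for Ttpa (-0.32) and Gpx4 (-0.0223). Sec14l2 (0.0102) turned for mixture against α-tocopherol. So did Cplx2 (0.00224), Ttpa (-0.25), Scarb1 (0.0411), Pltp (-0.0227) and the interferon response list (0.0654) for either supplement. With the Ttr signal as a covariate there was 1 α-tocopherol gene, 358 mixture genes, 1 either-supplement gene, 1 gene opposed by α-tocopherol and 203 genes opposed by the mixture. The direction changed for Ttpa (-0.0774) and Gpx4 (-0.0224) in α-tocopherol. Ttpa (-0.0661), Gpx4 (-0.0629) and Cat (-0.0626) turned for the mixture. So did Ttpa (0.0113) for mixture against α-tocopherol. For either supplement this held for Ttpa (-0.0717), Scarb1 (0.0566), Pltp (-0.0775), Gpx4 (-0.0426) and Cat (-0.0161). Leaving out old control mice 3 and 5 there were 0 mixture genes and 0 genes opposed by the mixture, and the mixture minus old control age score turned to 0.0214. A turn was seen for Ttpa (-0.0201), Pltp (-0.0667), Cat (-0.0233) and the interferon response list (0.0407) in α-tocopherol. So did Ttpa (-0.0252), Scarb1 (-0.14) and Cat (-0.13) for the mixture. For either supplement this held for Ttpa (-0.0227), Pltp (-0.16), Cat (-0.0760) and the interferon response list (0.0595).

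Leaving out single mice gave ranges of genes opposed by the mixture 110 to 334, Ttpa in α-tocopherol -0.0565 to 0.14, Scarb1 in α-tocopherol -0.15 to 0.0428, Pltp in α-tocopherol -0.0216 to 0.16, Cat in α-tocopherol -0.0172 to 0.15 and lists for α-tocopherol 3 to 8. Further ranges were the interferon response list in α-tocopherol -0.32 to 0.0544, mixture genes 186 to 593, Ttpa in the mixture -0.0308 to 0.0572, Scarb1 in the mixture -0.0253 to 0.17, Gpx4 in the mixture -0.0236 to 0.0605 and Cat in the mixture -0.12 to 0.11. The ranges also were either-supplement genes 0 to 184, Ttpa in either supplement -0.0257 to 0.0822, Scarb1 in either supplement -0.0890 to 0.11, Pltp in either supplement -0.11 to 0.0713, Cat in either supplement -0.0698 to 0.11 and the interferon response list in either supplement -0.30 to 0.0732. Last came the age score difference mixture minus old control -0.0862 to 0.0384, mixture against α-tocopherol genes 0 to 100, Ttpa in mixture against α-tocopherol -0.12 to 0.0769, Cat in mixture against α-tocopherol -0.18 to 0.00639 and lists for mixture against α-tocopherol 4 to 9.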

Other observations

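Gene lists not called for age had members that rose and fell. Among 24 unfolded protein response genes 2 rose and 4 fell (3 and 4 adjusted over the list alone, adjusted p = 0.923), and among 19 circadian clock genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.759). Of 16 endothelial genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.0756), of 11 pericyte and smooth muscle genes 2 rose (2 adjusted over the list alone, adjusted p = 0.13) and of 23 extracellular matrix genes 1 fell (1 adjusted over the list alone, adjusted p = 0.492). Of 24 heat shock genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.0812), of 37 antioxidant genes 5 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.13) and of 18 vitamin E and lipoprotein genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.0724).

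Neuronal lists of regions and classes were not called for age either. These were GABAergic interneuron genes (2 of 19 rose and 1 fell, adjusted p = 0.923), glutamate receptor genes (1 of 21 rose and 1 fell, adjusted p = 0.83), neuronal development genes (3 of 23 rose and 4 fell, adjusted p = 0.688), striatal genes (1 of 12 fell, adjusted p = 0.91), hippocampal genes (1 of 8 rose, adjusted p = 0.35) and cortical projection neuron genes (1 of 16 rose, adjusted p = 0.688). Adjusted over the list alone the counts were 2 and 1, 1 and 1, 4 and 5, 0 and 0, 0 and 0, and 1 and 0. Of 9 choroid plexus genes 1 fell (0 adjusted over the list alone, adjusted p = 0.0539), of 13 meninges genes 1 rose (1 adjusted over the list alone, adjusted p = 0.737) and of 5 lymphocyte and plasma cell genes 2 rose (2 adjusted over the list alone, adjusted p = 0.759). Median and mean differed in sign for the glutamate receptor (-0.04 and 0.03), unfolded protein response (-0.05 and 0.02), lymphocyte (-0.13 and 0.08), striatal (0.01 and -0.04) and GABAergic interneuron lists (-0.01 and 0.00).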
